A study of Homo sapiens with 4 samples.

How the data were processed

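The values are those of 4 Affymetrix arrays, 2 of monocytes treated with retinoic acid and 2 of monocytes treated with DMSO, labelled replicates A and B in each group. Per the labels' protocols, total RNA was extracted with Trizol, and 250 ng of it was amplified and biotin-labelled with the Affymetrix WT Plus chemistry. The submitters' processing notes name Affymetrix Expression Console and RMA (robust multi-array average: background correction, quantile normalization and summary of probes into probe sets), with no version. The deposited values are intensities on a linear scale, 1 per probe set and array, and not the log2 values that RMA itself gives. This was read from the values: each array ran from a shared minimum of 1.81, held by 1898 probe sets, to between 13014 and 13612. The genome build behind the probe sets is not given in the sources used here, so no coordinates are given. The values carry no detection call, so a low level cannot be told from background, and high intensities are compressed on such arrays.

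Of the 53617 probe sets, 16098 were paired with 1 gene symbol, 0 with several and 37519 with none by the platform annotation used here. The 16098 pairings covered 14884 genes, and all their symbols were found in the RefSeq table of GRCh38.p14, which served for biotypes and for which genes neighbour each other. XIST and Y-linked genes were left out, which left 14873 genes. Of the 778 genes with more than 1 probe set, the probe set with the highest mean over the 4 arrays was used; in 0 genes were probe sets called in opposite directions. Genes in the lowest 30% by mean level, at or under 5.07, were left out, and 10411 were tested. Probe sets of near-identical genes, such as HSPA1A and HSPA1B or CXCR1 and CXCR2, can share signal. RARA, RARB, CYP26A1, CYP26B1, TGM2 and MRC1 had no probe set named here and were not analysed here.

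Intensities were transformed to log2(intensity + 1), so fold changes are on that scale and understate the change of dim genes. Retinoic acid was compared with DMSO by limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend and not robust), with no block, in a two-sided test. The p-values were adjusted by Benjamini-Hochberg over all genes tested, and genes with an adjusted p under 0.05 were called changed. The model had 2 residual degrees of freedom and borrowed 4.16 from the other genes, with a prior SD of 0.106. The SE given beside a log2 fold change is that of the moderated fit. The SE given beside a median over marker genes comes from the spread between those genes, taken as independent. It does not measure the spread between arrays. All p-values beside single genes come from this limma model.

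Before the data were examined, 27 gene lists were fixed for retinoid biology, the dendritic cell, macrophage and monocyte lineages, their functions, and other cell types of blood. The 25 lists with at least 5 tested members were tested by limma's camera with a preset correlation between genes of 0.01, two-sided and adjusted over the 25 lists. These p-values rest on the spread between genes, taken as nearly independent, and do not measure the spread between arrays. With the correlation estimated from each list's residuals, 0 of the 25 lists passed, and 2 had an unadjusted p under 0.05. This estimate rested on 2 residual degrees of freedom, which left little power, so a list that missed here was not shown to be unshifted. By fry, which asks whether a list's genes move on balance in a direction without comparing them with other genes, 10 lists passed. These included the 4 that passed with the preset correlation. The others were retinoid metabolism, macrophage markers, lineage transcription factors, LXR and PPAR gamma targets, proteases and matrix, and immediate early genes. A list said below not to have shifted missed the threshold of camera with the preset correlation. Counts of changed members are given over all genes and adjusted over the list alone. Genes were named by a rule fixed at the same time. It took the 12 highest and 12 lowest log2 fold changes among changed genes whose groups did not overlap. It added up to 4 members of each list, or 6 of each of the first 7 lists, with the smallest p-values, and 15 genes of interest whatever their values. Members without an adjusted p under 0.05 were named only where the text needed them. Where the text names other genes, it says so.

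The procedure was tested on simulated data with the mean levels of these 10411 genes, 200 of them changed. Variances were drawn from the distribution that limma fitted, whatever the level of the gene, and the noise was normal and independent between genes. The procedure recovered 20% of the 50 genes changed by a log2 fold of 0.5, 94% of those changed by 1 and 100% of those changed by 2 or 3. It made 8 false calls among 165. The simulated data met the assumptions of the model, so this count does not show the false calls to expect where real arrays depart from them.

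The alternatives fixed before the data were examined changed the filter on dim genes, the choice among probe sets, the scaling, the block, the moderation of the variance, the array weights, the threshold and the list test, and left out each array in turn. The log2 transformation without a pseudocount and the test of every named probe set on its own were added after the data were seen. The 37519 probe sets without a gene name were kept out of the comparisons and tested separately with the same model.

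The 3 tests on cell types were set after the result was seen and were changed after their own values were seen. The difference between CD1A and IRF4 (-2.78, SE 0.17) had been read against a lower share of dendritic cells, but it rests on the deepest fall of the lists. The median of all 5 neutrophil markers (0.0689, SE 0.510) had been read against more neutrophils, at first as it stood and then with at least 3 markers required above the level minimum; it is the value of a dim gene, and the test now uses only markers above the minimum and asks for a gap of 2 SE, which was chosen with the earlier outcome known. The median of 24 T, NK, B cell and platelet markers (-0.00540, SE 0.117) had been read against a loss of these cells, though most of them are dim.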

Results

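Gene expression was measured on 4 Affymetrix arrays of human monocytes from normal donors, cultured with GM-CSF and interleukin 4 at 50 ng/ml each, the cytokine pair that turns monocytes into dendritic cells. Of the 4 arrays, 2 were of cells given 20 nM all-trans retinoic acid, the active form of vitamin A, and 2 of cells given the solvent DMSO. RNA was taken 24 h later. Each group held a replicate A and a replicate B. The arrays had closely similar median intensities over their 53617 probe sets, of 31.8 and 31.3 with retinoic acid and 31.3 and 31.0 with DMSO. After the log2 transformation, the arrays correlated across 10411 genes with r = 0.993 between the retinoic acid replicates, 0.992 between the DMSO replicates and 0.966 to 0.969 between the groups. These correlations run across genes, which are not independent replicates. The number of arrays limits the precision of every value, and levels are given as log2(intensity + 1).

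The comparison asked which genes retinoic acid changed in monocytes on their way to dendritic cells. The highest rise was that of VSIG4, a complement receptor of tissue macrophages, from a mean level of 6.45 with DMSO to 10.91 with retinoic acid, a log2 fold change of 4.46 (SE 0.10, 22.0-fold, n = 2 arrays per group). CCL2, a chemokine that attracts monocytes, rose by 4.36 (SE 0.14, 20.5-fold), and DHRS3, which reduces retinaldehyde to retinol, rose by 3.85 (SE 0.10, 14.5-fold). The deepest fall was that of MMP12, the macrophage elastase, from 9.13 with DMSO to 4.39 with retinoic acid, a log2 fold change of -4.73 (SE 0.16, 26.6-fold lower). The 4.39 lies under the level of 5.07 that the mean of a gene had to exceed for a test and is not told from background, so this fold is a lower bound. NPR1, a receptor of natriuretic peptides, followed with -3.99 (SE 0.15), and CD1A, which presents lipid antigens on dendritic cells, with -3.71 (SE 0.14). All 6 genes passed limma's test with adjusted p-values between 4.6e-05 and 9.6e-05.

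Among the 12 highest rises were also the immunoglobulin-like myeloid receptors CD300LB (3.82) and CD300LF (3.07), the secreted glycoprotein LRG1 (3.74) and the transcription factors HIC1 (3.56) and HIVEP2 (3.44). The matrix protein THBS1 (3.30), ANKRD22 (3.10), TBL2 (2.92) and CHST15, a chondroitin sulfate sulfotransferase (2.81), completed them. The 12 deepest falls went on with SOBP (-3.52), CTTNBP2 (-2.30), the cytidine deaminase CDA (-2.22), EMP1 (-2.03) and GFRA2 (-2.01). They ended with the fatty acid receptor FFAR4 (-1.98), the chemokine CCL23 (-1.95), the metalloprotease ADAM19 (-1.85) and RAP1GAP (-1.85). The DMSO level of ANKRD22, 4.82, was also under 5.07, so its fold is a lower bound too. The SE of these log2 fold changes lay between 0.09 and 0.20.

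**Figure D1:**
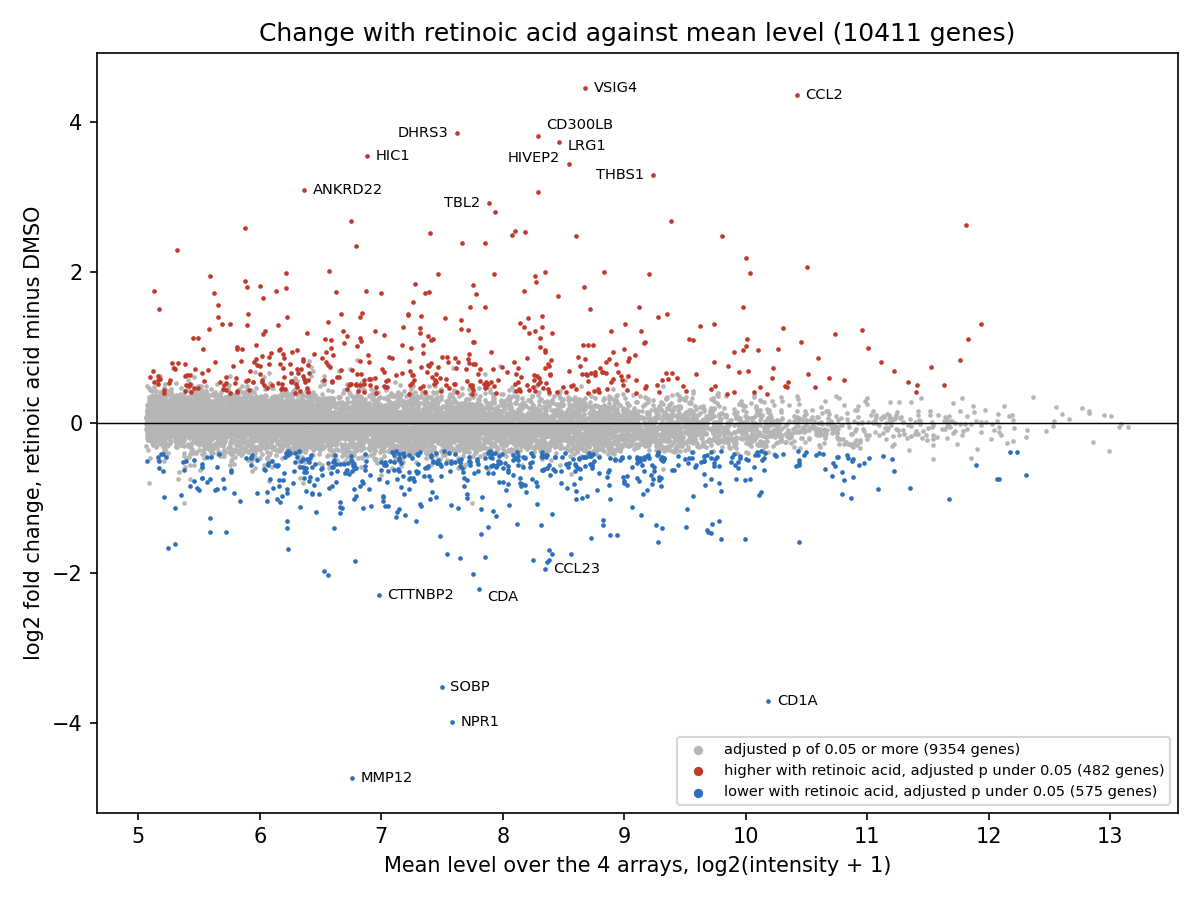
Log2 fold change (retinoic acid minus DMSO) against the mean level over the 4 arrays, as log2(intensity + 1), 1 point per tested gene. Red points are the 482 genes that rose and blue points the 575 that fell; VSIG4 at 4.46 and MMP12 at -4.73 are the extremes.

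In all, 1057 of the 10411 tested genes (10.2%) changed with retinoic acid, 482 upward and 575 downward. At least 2-fold changes were seen in 144 raised and 93 lowered genes, and at least 4-fold changes in 31 raised and 8 lowered genes. The other end held 433 changed genes that moved by less than 1.5-fold. In all 1057 genes both arrays of a group lay on the same side of both arrays of the other group, and the fold change had the same sign in A and in B. With 2 arrays per group a gene whose groups overlap could not pass the threshold. Neither statement is therefore a separate sign of reproducibility. Over all tested genes the groups were apart in 5857 genes (56.3%), where chance gives 33.3%. Protein-coding genes (9090 tested) supplied 438 of the raised and 529 of the lowered genes, long non-coding RNAs (614 tested) 22 and 21, and microRNA genes (423 tested) 17 and 15. Some of these microRNA genes overlap a changed gene that moved the same way, and their signals were not told apart. Across all tested genes the log2 fold changes of A and B correlated with r = 0.773. The larger share of falls did not hold after quantile normalization (532 raised and 477 lowered), without retinoic acid replicate A (252 and 183) or without DMSO replicate B (376 and 368). The labels do not say that replicates came from separate donors or cultures, so the p-values of single genes measure only the spread between these arrays, which may be technical. Leaving out an array lowered the count, to 435 genes without retinoic acid replicate A, 474 without retinoic acid replicate B, 895 without DMSO replicate A and 744 without DMSO replicate B.

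Retinoic acid targets rose. Of 7 tested members of the list of retinoic acid receptors and inducible targets, 5 rose and 0 fell, with the same counts when adjusted over the list alone, and the median log2 fold change was 1.31. They were HIC1 (3.56, SE 0.14), the NAD-consuming surface enzyme CD38 (2.54, SE 0.14), the nuclear receptor cofactor NRIP1 (2.19, SE 0.09), the ubiquitin ligase subunit ASB2 (1.31, SE 0.12) and PLAAT4 (0.45, SE 0.09). The list shifted upward against all other genes (camera adjusted p = 1.8e-05), but not with the correlation estimated from the data (adjusted p = 0.495 with an estimated correlation). In the list of retinoid metabolism and handling, 2 of 7 members rose and 1 fell, again the same when adjusted over the list alone. DHRS3 was joined by RDH11, a retinal reductase (0.65, SE 0.09), while BCO2, which cleaves carotenoids, fell (-0.46, SE 0.10). That list was not shifted by camera (adjusted p = 0.266) but passed upward by fry (adjusted p = 0.0419).

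Dendritic cell markers fell. Of 12 tested members of the list of monocyte-derived dendritic cell markers, 5 fell and 0 rose, and 9 fell when adjusted over the list alone, with a median log2 fold change of -0.48. CD1A went from a level of 12.04 (SD 0.02, n = 2) with DMSO to 8.33 (SD 0.28, n = 2) with retinoic acid. Its relatives CD1E (-0.87), CD1B (-0.70) and CD1C (-0.65) and the transcription factor IRF4 (-0.93) also fell, each with an SE of 0.09 or 0.10. The lectin CD209 had a log2 fold change of -0.30 (limma adjusted p = 0.093) and the transcription factor ZBTB46 one of -0.45 (limma adjusted p = 0.056), so neither passed over all genes; a second probe set of ZBTB46 had 0.30. The list shifted downward (camera adjusted p = 5.6e-05, or 0.672 with an estimated correlation). In 11 of its 12 members retinoic acid replicate B stood above retinoic acid replicate A. The median of B minus A was 0.12 with retinoic acid and -0.02 with DMSO, so the fall was smaller in B. The list of the interleukin 4 response shares 3 of its 11 tested members, IRF4, CCL17 and CCL22, with the dendritic cell list. The falls of both lists are therefore partly those of the same genes. In the interleukin 4 list 4 fell and 0 rose, and 9 fell when adjusted over the list alone. These 4 were CCL23, IRF4, the monoamine oxidase MAOA (-0.89, SE 0.11) and the inhibitory receptor CD200R1, whose level went from 11.37 with DMSO to 10.37 with retinoic acid. CCL18 had -0.61 (limma adjusted p = 0.0507) and FGL2 -0.38 (limma adjusted p = 0.0521). This list had a median of -0.49 and shifted downward (camera adjusted p = 2.1e-06, or 0.672 with an estimated correlation). Here too retinoic acid replicate B stood above retinoic acid replicate A, in 10 of 11 members and by a median of 0.13.

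Monocyte markers rose. Of 12 tested members of that list 10 rose and 0 fell, with the same counts when adjusted over the list alone, and the median log2 fold change was 1.10. The largest rises were those of the proteoglycan VCAN (1.68, SE 0.10), the calcium-binding protein S100A8 (1.45, SE 0.09) and the lectin FCN1 (1.26, SE 0.09). CD14, the lipopolysaccharide co-receptor, rose by 1.22 (SE 0.10), PLBD1 by 1.17 (SE 0.10) and S100A9, the partner of S100A8, by 1.03 (SE 0.09). The list shifted upward (camera adjusted p = 4.0e-11; adjusted p = 0.495 with an estimated correlation). Macrophage markers went both ways, with 3 of 13 rising and 2 falling, or 4 rising and 3 falling when adjusted over the list alone. VSIG4, the haemoglobin scavenger receptor CD163 (1.80, SE 0.14) and the protease LGMN (0.84, SE 0.12) rose, and the transcription factor MAF (-0.98, SE 0.11) and the scavenger receptor STAB1 (-0.55, SE 0.09) fell. The list's median was -0.01, its mean 0.40 and its test upward without passing (camera adjusted p = 0.542). It passed upward by fry (adjusted p = 0.0252).

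**Figure D2:**
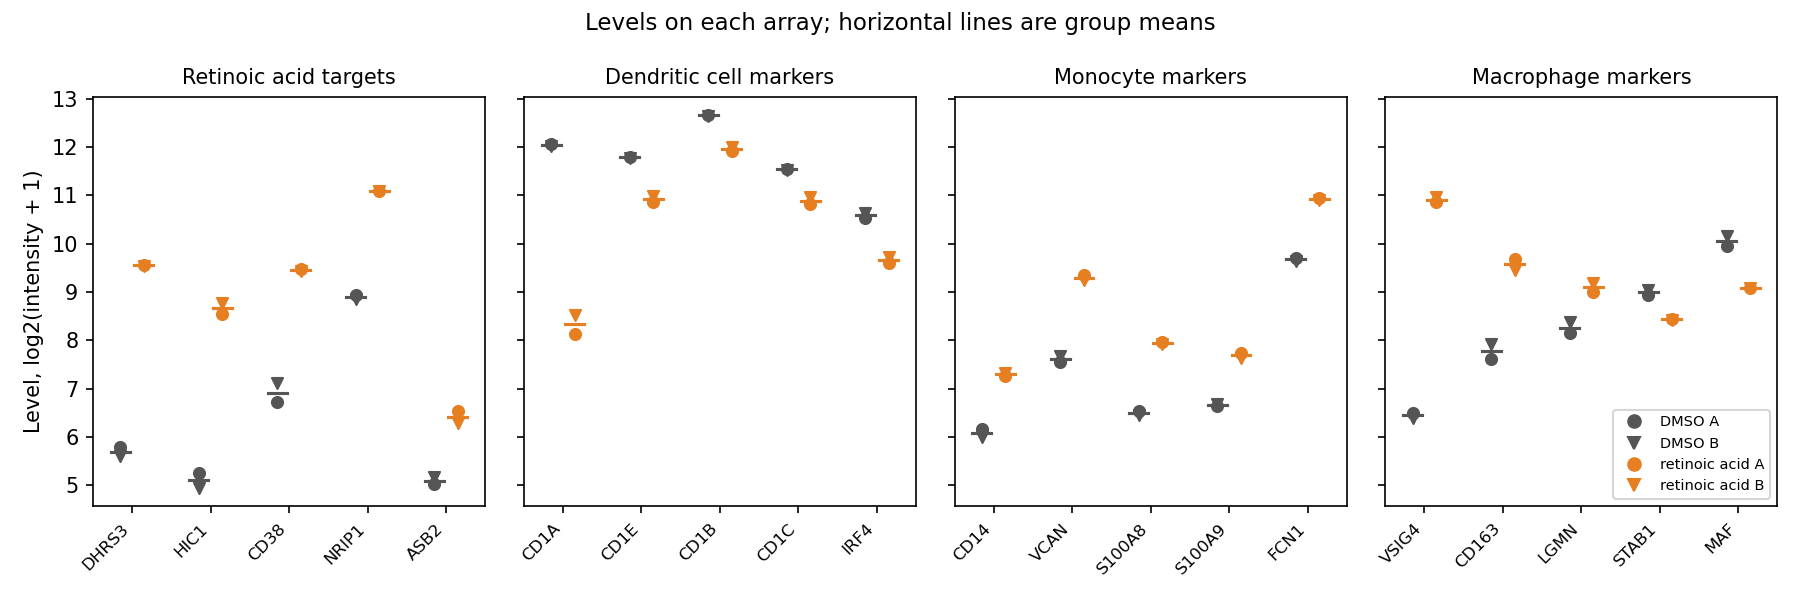
Level of 20 genes on each of the 4 arrays, as log2(intensity + 1), in 4 panels of retinoic acid targets, dendritic cell, monocyte and macrophage markers. Grey symbols are DMSO and orange symbols retinoic acid, circles replicate A and triangles replicate B, lines the group means; CD1A lies near 12.04 with DMSO and 8.33 with retinoic acid.

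Of 9 tested lineage transcription factors 1 rose and 3 fell, or 1 and 4 when adjusted over the list alone. IRF8 rose (0.46, SE 0.10), and MAF, IRF4 and the aryl hydrocarbon receptor AHR (-0.39, SE 0.09) fell. The list was not shifted by camera (adjusted p = 0.250) but passed downward by fry (adjusted p = 0.0252). Among 11 genes of costimulation and dendritic cell maturation 2 fell and 0 rose, also when adjusted over the list alone: CD80 (-1.39, SE 0.17) and PDCD1LG2 (-1.04, SE 0.15). CD86, the other main ligand of CD28 beside CD80, had 0.29 (limma adjusted p = 0.096), and the list was not shifted (camera adjusted p = 0.338). Of 7 inflammatory cytokines and chemokines CCL2 rose and TNF fell (-1.02, SE 0.14), also when adjusted over the list alone. This list had a median of -0.04, a mean of 0.43 and an upward test that did not pass (camera adjusted p = 0.823). Of 10 immunoregulatory molecules 1 rose and 3 fell, also when adjusted over the list alone. VEGFA rose (0.55, SE 0.10), and PDCD1LG2, IL10 (-0.74, SE 0.14) and the ectonucleotidase ENTPD1 (-0.42, SE 0.09) fell, with no shift of the list (camera adjusted p = 0.330). For MHC class II presentation only 2 of 14 genes were tested, too few for a list test. Of these LGMN rose, and the other did not pass, also when adjusted over the list alone.

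Genes of the extracellular matrix and its turnover changed in both directions. Of 12 proteases, matrix and tissue remodelling genes 4 rose and 1 fell, or 5 and 1 when adjusted over the list alone. FN1, fibronectin, rose by 2.63 (SE 0.09, 6.18-fold), THBS1 by 3.30 (SE 0.10) and the protease inhibitor TIMP1 by 1.00 (SE 0.10), while MMP12 fell. The list was not shifted by camera (adjusted p = 0.103), though it was with the lowest 50% of genes left out (adjusted p = 0.0306). It passed upward by fry (adjusted p = 0.0252). Of 6 genes of integrins, homing and adhesion 2 rose and 0 fell, or 2 and 1 when adjusted over the list alone. They were CCR2, the receptor of CCL2 (1.08, SE 0.11), and ICAM1 (0.54, SE 0.12), with no shift of the list (camera adjusted p = 0.330).

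Of 11 LXR and PPAR gamma targets 1 rose and 3 fell, or 1 and 4 when adjusted over the list alone. The apolipoprotein APOC1 rose (1.13, SE 0.15, a lower bound from a DMSO level of 4.93). The fatty acid transporter CD36 (-0.84, SE 0.10), the carnitine palmitoyltransferase CPT1A (-0.80, SE 0.10) and the desaturase SCD (-0.74, SE 0.11) fell. The list was not shifted by camera (adjusted p = 0.330) but passed downward by fry (adjusted p = 0.0444). Of 10 cholesterol biosynthesis genes 1 rose and 3 fell, or 2 and 6 when adjusted over the list alone. SQLE (-0.66, SE 0.09), HMGCS1 (-0.56, SE 0.09) and MSMO1 (-0.53, SE 0.10) fell and DHCR7 (0.53, SE 0.09) rose, with no shift (camera adjusted p = 0.266). Of 9 genes of glycolysis and hypoxia VEGFA rose and BNIP3 fell (-0.64, SE 0.09), or 2 rose and 1 fell when adjusted over the list alone, with no shift (camera adjusted p = 0.274). Of 14 immediate early and heat shock genes 4 fell and 0 rose, or 5 and 0 when adjusted over the list alone. The transcription factors JUN (-1.50, SE 0.13) and FOS (-0.63, SE 0.09), the phosphatase DUSP1 (-0.75, SE 0.09) and IER3 (-0.63, SE 0.10) made up the 4. The list missed the threshold of camera (adjusted p = 0.0931) but passed without a filter on dim genes (camera adjusted p = 0.0253). It also passed downward by fry (adjusted p = 0.0395).

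**Figure D3:**
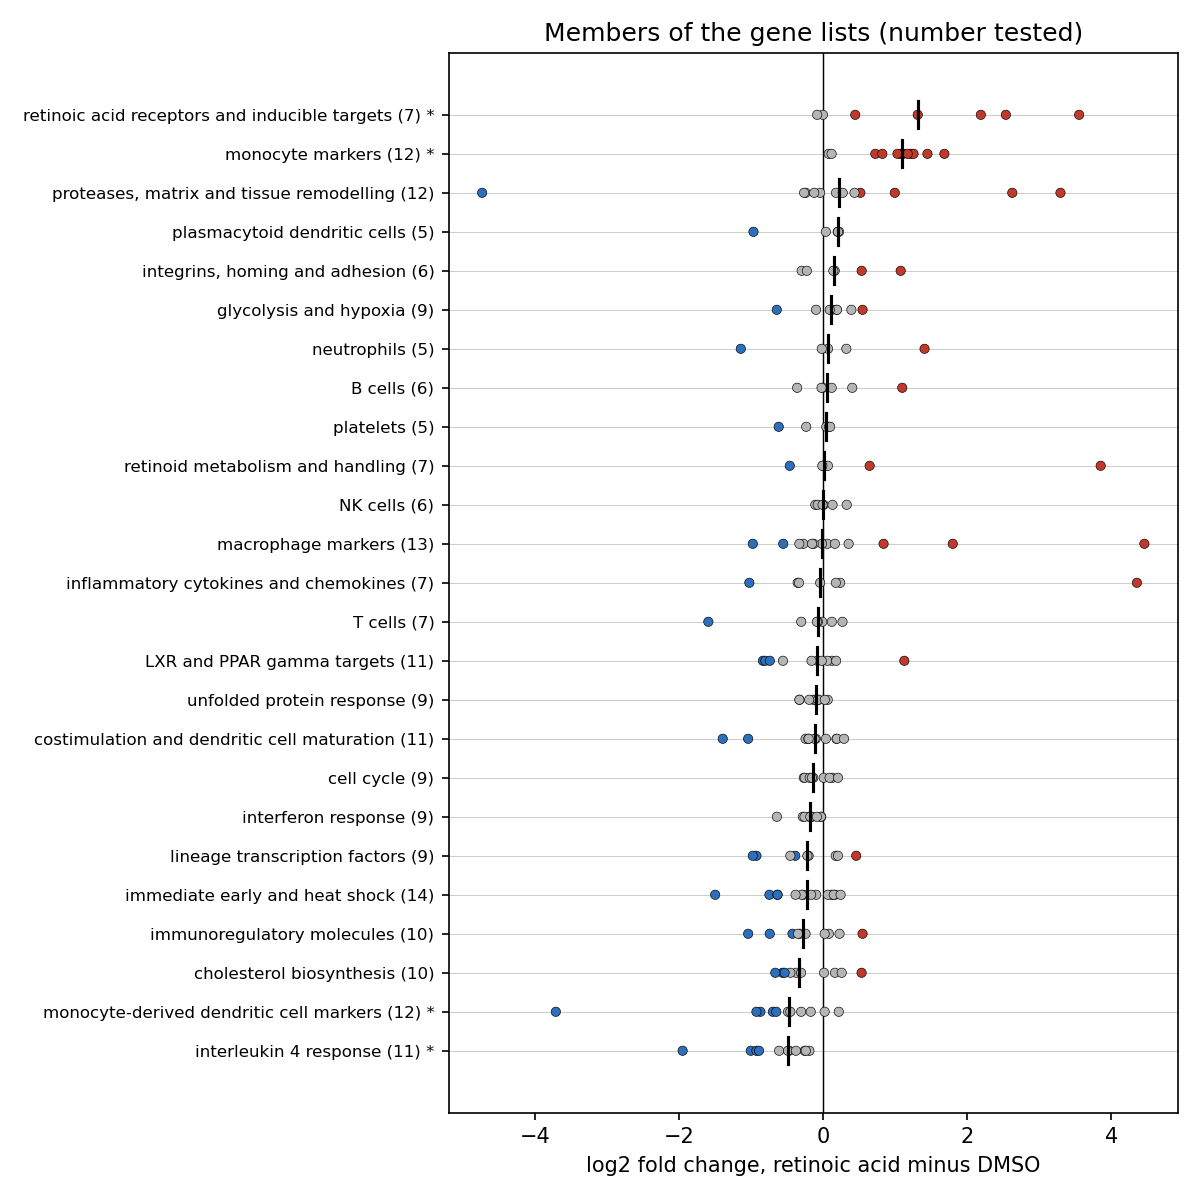
Log2 fold change (retinoic acid minus DMSO) of each tested member of the 25 lists with at least 5 tested members, 1 line per list with the number tested, and a black bar at the list's median. Red members rose, blue members fell and grey members did not pass over all genes; an asterisk marks the 4 lists that shifted with the preset correlation, of which 0 did with an estimated correlation.

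No gene passed in 4 of the lists, also when adjusted over the list alone: the interferon response (9 tested), the cell cycle (9), the unfolded protein response (9) and NK cells (6). Their camera adjusted p-values were 0.542, 0.577, 0.330 and 0.564, and at an unadjusted p under 0.05 by limma they held 0, 2, 1 and 1 genes. The interferon genes stood higher in DMSO replicate B than in DMSO replicate A. Without DMSO replicate A the interferon list was lower with retinoic acid (camera adjusted p = 4.8e-06), and without DMSO replicate B it was higher (camera adjusted p = 0.00872).

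None of the lists of markers of other blood cells shifted, and each call below stood also when adjusted over the list alone unless another count is given. Of 7 T cell markers IL7R fell (-1.59, SE 0.16), of 5 platelet markers TREML1 fell (-0.62, SE 0.10), and of 5 plasmacytoid dendritic cell markers NRP1 fell (-0.97, SE 0.11). Of 6 B cell markers CD22 rose (1.10, SE 0.10), with 2 rising and 1 falling when adjusted over the list alone. Of 5 neutrophil markers the interleukin 8 receptor CXCR2 rose (1.41, SE 0.13) and its close relative CXCR1 fell (-1.14, SE 0.12); their similar sequences could share probes. The camera adjusted p-values were 0.542 for T cells, 0.607 for platelets, 0.630 for plasmacytoid dendritic cells, 0.330 for B cells and 0.564 for neutrophils. The platelet list had a median of 0.05, a mean of -0.12 and a downward test. The plasmacytoid list had a median of 0.20, a mean of -0.06 and an upward test. No red blood cell marker was tested, since 8 of the 10 had no probe set named here and 2 were too dim.

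Of the 77 genes named by rule that passed, 22 lost their call when 1 array was left out, with adjusted p-values up to 0.207 without retinoic acid replicate A, 0.176 without retinoic acid replicate B, 0.128 without DMSO replicate A and 0.124 without DMSO replicate B. These were RDH11, BCO2, PLAAT4, CD1B, CD1C, LGMN, STAB1, IRF8, AHR, VEGFA, IL10, ENTPD1, SCD, SQLE, HMGCS1, DHCR7, MSMO1, BNIP3, FOS, IER3, ICAM1 and TREML1; all kept their direction. With the mean of a gene's probe sets in place of the brightest, HIVEP2 rose by 1.82, NRIP1 by 1.37 and VCAN by 1.00, ZBTB46 had -0.08, and SCD (-0.34) and IER3 (-0.37) lost their calls.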

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

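The test of probe sets without a gene name was chosen after the main result was seen, and so were the 3 tests on cell types below, which replaced earlier tests whose values had been seen.

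A signal appeared in data outside the main comparison. Of 37519 probe sets that had no gene name here, 15192 lay above the level minimum of the tested genes, and 218 of these (1.43%) changed with retinoic acid in the same limma model, 106 upward and 112 downward. Among named genes, adjusted separately, the share was 10.2%. At an unadjusted p under 0.05 by limma the gap was smaller, with 2412 of the 15192 unnamed probe sets and 2732 of the 10411 named genes. Of the 218 changed ones, 84 rose and 90 fell at least 2-fold. What these probe sets measure was not analysed here.

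Monocyte markers had a median log2 fold of 1.10 (10 of 12 rose). Dendritic cell markers had one of -0.48 (5 of 12 fell and 7 did not pass). Neither list passed camera with an estimated correlation (adjusted p = 0.495 and 0.672), which rested on 2 residual degrees of freedom. Both passed by fry (adjusted p = 0.0128 and 0.0381). Loss of T, NK or B cells or platelets that diluted the monocytes would raise the dendritic cell markers like the monocyte markers. The median of the dendritic cell markers, -0.48 (SE 0.363, from the spread over genes), lay below 1.10 by more than 2 SE. Such a loss alone would not give this gap. The gap is, however, the pattern itself and was known before the test was set, so the test adds no evidence. Most markers of those cells were too dim to decide. IL7R and TREML1 fell, CD22 rose (1.10), and the platelet markers PPBP (-0.23) and PF4 (0.10) did not pass. A lower share of cells that became dendritic cells stays open: beside CD1A the 7 other changed members all fell, over a range of 1.30 (largest SE 0.14), and how much of these transcripts the other cells held was not analysed here. More neutrophils stay open too, since of 3 markers well above the level minimum CXCR2 rose by 1.41, CXCR1 fell and CEACAM3 did not pass (median -0.0181, SE 0.925). That retinoic acid may hold the cells closer to monocytes is a hypothesis, since no cells from before the culture were analysed here.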

How the results depend on the processing

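The settings without a pseudocount and with every named probe set on its own were chosen after the result was seen; the others were planned.

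The 1057 changed genes became 1816 with a variance trend, 1701 at an adjusted p under 0.10, 624 with a fold of at least 1.5, and 666 at an unadjusted p under 0.05 with that fold. Leaving out each array in turn gave 435 to 895, with 435 and 474 without retinoic acid replicates A and B; fewer arrays were fitted there, and the lone array left in a group is assumed to vary like the other group. All other settings gave 844 to 1390. The cause of the higher count with a trend was not tested; it kept 1034 of the 1057 genes. With the letters as a replicate block 1386 genes passed, all 1057 among them. The labels do not say whether the letters pair the arrays, so a pairing stays open. Same-lettered arrays deviated together with r = 0.108. More genes rose than fell after quantile normalization (532 and 477), without retinoic acid replicate A (252 and 183) or DMSO replicate B (376 and 368), with the 1.5-fold threshold (316 and 308), and with that and an unadjusted p (334 and 332). Scaling moved the median of all genes from -0.01 to 0.01 or -0.03.

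Retinoic acid targets, monocyte markers, dendritic cell markers and the interleukin 4 response passed in every setting of camera with a preset correlation that tested them. The immediate early list joined them without a filter (0.0253), the protease list with the lowest 50% left out (0.0306), and the interferon list without either DMSO array. With an estimated correlation, which rested on 2 residual degrees of freedom, 0 lists passed. By fry 10 passed, the 4 lists of the main result among them. The other lists that passed by fry had missed camera with the preset correlation, so that miss does not show them to be unshifted. With an estimated correlation the adjusted p was 0.495 for retinoic acid targets and monocyte markers and 0.672 for dendritic cell markers and the interleukin 4 response. Over the other camera settings it stayed between 2.2e-06 and 6.1e-05, 5.6e-14 and 2.9e-10, 6.6e-06 and 0.000398, and 3.2e-08 and 2.7e-05 in that order. With the lowest 50% left out, too few retinoic acid targets remained for a test. The correlation of A and B was 0.688 without a filter and 0.841 with the lowest 50% left out, where fewer dim genes were counted.

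Directions turned in 5 lists not called: the inflammatory list (adjusted p 0.527 to 0.920 over the arrays left out; turned at 0.920 and 0.866), the interferon response (4.8e-06 to 0.701; turned at 0.00872 without DMSO replicate B), NK cells (0.246 to 0.920; turned at 0.786), plasmacytoid dendritic cells (0.528 to 0.929; turned at 0.836, and at 0.598 by fry) and the cell cycle (0.771 with the lowest 50% left out). The cause was not tested. The settings that gave 1 value per gene were checked for 82 genes named by rule, 77 that passed and 5 that had not. None of these 82 turned, while second probe sets had 0.30 for ZBTB46 and 0.07 for SCD. Other genes picked by the rule that had not passed, such as PPBP and PF4, were left out of this check. Of the 77, 6 lost the call without a filter (BCO2, PLAAT4, IRF8, AHR, ENTPD1, ICAM1) and 2 with the mean of the probe sets (SCD, IER3). Calls were also lost by 2 with quantile normalization (AHR, ENTPD1) and 1 without a pseudocount (AHR). The mean of the probe sets also lowered HIVEP2 to 1.82, NRIP1 to 1.37 and VCAN to 1.00. The 5 of these 82 genes that had not passed did so with a variance trend. Signal over background was not measured, and dim genes are the least certain.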

Other observations

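The tests of gene families were chosen after the fold changes of all genes were seen, so the p-values of the families describe these data and are no independent evidence. The tests weighed for neighbouring and for zinc finger genes were set before their own results were seen. The 15 genes named here outside the lists were chosen after their values were seen, and each passed in every alternative setting that gave it a value.

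Of 19 gene families tested with camera and adjusted over the families, 2 shifted with retinoic acid, and 0 did with an estimated correlation (1 at an unadjusted p under 0.05). CD300 receptors, which tune myeloid cells, shifted upward with a median log2 fold of 1.14 over 6 genes (adjusted p = 4.1e-06; adjusted p = 0.600 with an estimated correlation). Of these 3 rose and 0 fell, CD300A by 1.84 (SE 0.11) beside CD300LB and CD300LF. The rises of CD300LB and CD300LF, among the highest of all genes, were known before the family was tested, so its p-value adds no evidence. CD300A and CD300LB are neighbours of like symbols and could share probes. Toll-like receptors had 4 of 9 members raised and 0 lowered, or 2 raised when retinoic acid replicate A or B was left out, 3 without DMSO replicate A and 1 lowered after centring, with TLR8 at 1.73 (SE 0.09) and TLR5 at 1.39 (SE 0.16), and the family missed the threshold (adjusted p = 0.0615; 0.00824 to 0.119 over other scalings and arrays left out, under 0.05 only without DMSO replicate B). Among interleukin receptors IL31RA rose by 1.51 (SE 0.12, a lower bound from a dim DMSO level of 4.42) and 4 of 16 fell, IL1RAP among them at -1.35 (SE 0.11); the family also missed it (adjusted p = 0.0615; 0.0314 to 0.119 over the same, with 0.0454 without DMSO replicate B and 0.0314 after quantile normalization). Other families passed in some settings only: mitochondrial ribosomal proteins (0.0173) and ribosomal proteins (0.0278) after quantile normalization, the former also without retinoic acid replicate A (0.0411), and GPR receptors without DMSO replicate A (0.0475).

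The eotaxins CCL26 (2.68, SE 0.11) and CCL24 (1.32, SE 0.10), both known to be induced by interleukin 4 and on none of the fixed lists, rose. All 11 tested members of the interleukin 4 list had a negative log2 fold. Of these 4 fell and 7 did not pass, or 9 fell when adjusted over the list alone. The list passed camera with the preset correlation (adjusted p = 2.1e-06) and fry (adjusted p = 0.0341). It missed the threshold with an estimated correlation (camera adjusted p = 0.672), as did all 25 lists. ALOX5 (1.31, SE 0.09) and ALOX5AP (1.99, SE 0.11), which make leukotrienes, rose together. MYB, a transcription factor of blood progenitors, rose by 2.68 (SE 0.19), and CD1D, unlike the other CD1 genes measured, by 2.48 (SE 0.13).

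In the interferon list DMSO replicate B lay above DMSO replicate A in 9 of 9 genes, by a median of 1.19.

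Genes that neighbour each other changed alike. Over 10386 pairs of adjacent tested genes the log2 fold changes correlated with r = 0.127 (Spearman 0.121), against at most 0.0407 in 10000 shuffles of the fold changes over the genes (permutation p = 1e-04, the smallest they can give), which argues against chance order. Without pairs of like symbols or overlapping spans r was 0.0942 over 8811 pairs (permutation p = 1e-04), which argues against probes shared by such pairs as the whole cause; paralogs of unlike names stayed in and could share probes, and 87 pairs of changed genes moved the same way and 42 opposite ways. Examples are VSIG4 with MIR223 (2.52, SE 0.10), CD38 with its paralog BST1 (0.96, SE 0.09), and TBL2 with MLXIPL (2.02, SE 0.09) and BCL7B (0.76, SE 0.09). Control of neighbouring genes by shared regulatory elements may contribute, and was not tested.

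Zinc finger genes named ZNF were lower with retinoic acid, with a median log2 fold of -0.166 over 388 genes, of which 42 fell and 1 rose (camera adjusted p = 4.1e-06; adjusted p = 0.600 with an estimated correlation). The median was -0.172 in A and -0.150 in B, -0.144 after quantile normalization and -0.183 after centring, and 4 genes fell without retinoic acid replicate A and 11 without retinoic acid replicate B. Random lists of the same size and levels had medians between -0.0176 and 0.0308 in the middle 95%, which argues against a shift that depends on the level. Off chromosome 19, where many of these genes lie in clusters, the median was -0.129 over 201 genes, against -0.0369 to 0.0345 in matched lists, which argues against probes shared in those clusters as the whole cause; on it the median was -0.252 over 187 genes with 29 of the 42 falls, so shared probes may add to the fall there. Zinc finger transcripts are known to be short-lived, and a change in turnover may contribute; this was not tested.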
